A study of Tachycineta bicolor with 40 samples.

How the data were processed

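RNA was extracted from a ventral and a dorsal brain sample of each of 20 female tree swallows with a phenol-chloroform (Trizol) method, and libraries were made with a stranded mRNA kit (TruSeq), per the labels' protocols. Reads were processed by the authors with Trimmomatic 0.36, Bowtie2 2.3.4.1 and SAMtools, per the submitters' processing notes. How reads were assigned to contigs, whether strand was used and which assembly the contigs come from are not given in the sources used here. The deposited files hold raw counts, as whole numbers per contig, with 1 file per library and the same 207747 contig IDs in each. The counts were used as deposited. Contigs that share sequence can share or trade reads when reads are assigned, so contigs of one ID stem are not independent, and a read may count for a near-identical contig.

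Groups came from the labels of region and treatment, and bird numbers from the labels pair the 2 libraries of a bird. The ventral library of bird 21, marked as excluded by the submitters, was left out of all main comparisons, and with it bird 21 from the within-bird comparisons, which used 19 birds. No pair of the 40 libraries was a duplicate: the smallest chi-square per degree of freedom of any pair was 6.277. It was taken over contigs with a high total over all libraries and at least 10 counts in the pair. As a check of the pairing, deviations from group means were correlated across contigs between the 2 libraries of a bird. These correlations ran from 0.371 to 0.743 in 18 birds, each of which matched its own bird best, and the value was -0.0243 in bird 40.

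Contigs with too few counts were removed with filterByExpr, libraries were scaled by TMM, and counts were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. Intrusion was compared with control in each region alone. The regions were compared within birds, with bird number as a block, and the interaction of treatment and region was tested with the same block. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic, and 95% confidence intervals from these. CPM values are TMM-scaled within the libraries of each comparison, and log2 CPM used a prior count of 2. For the correlation of intrusion effects between regions, the effect was the difference of group means of log2 CPM, scaled over all libraries. That correlation was set against 100 reassignments of whole birds.

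The test was tried on simulated counts with the means and spread of the real contigs, in which 200 contigs were changed. Counts were drawn independently for each contig and library, so differences shared by many contigs or by the libraries of a bird were absent. The 200 changes also entered together, which loosens the adjustment compared with 1 changed contig. The shares below may therefore not carry over to the real birds. Of 1.5-fold, 2-fold and 4-fold changes, 22.4%, 47.8% and 92.4% were recovered in the ventral comparison (4 false calls among 71490 contigs) and 17.9%, 56.7% and 87.9% in the dorsal comparison (0 among 68907). For the region comparison the shares were 49.3%, 85.1% and 90.9% (4 among 80240), and for the interaction 16.4%, 49.3% and 90.9% (7 among 80240). With the libraries of each bird summed they were 22.4%, 58.2% and 78.8% (5 among 92688).

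Before the data were examined, the comparisons, the tests, the naming rule, most alternatives and 29 gene lists were fixed. The contig IDs carry no gene symbols, and no annotation of them was used here, so the gene lists, the cell type markers and the genes to be named by symbol could not be matched to contigs and were not analysed here. For contigs without a symbol the rule named at most 2 higher and 2 lower contigs per comparison. Among contigs past the threshold with a mean of at least 1 CPM, and, between regions, with one direction in every bird, these were the largest by log2 fold change. Where none passed, they were the contigs of smallest p in each direction, at any mean. Contig tree_swallow021090t2 and contig tree_swallow009209t3 were named after their values were seen.

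Alternatives were DESeq2 size factors, no filter on low counts, a filter of at least 5 CPM, the DESeq2 1.42.0 Wald test, robust quasi-likelihood, a threshold of 0.1, all 4 groups in 1 fit, limma 3.58.1 (voom with sample quality weights, and voom with bird as a random effect), keeping the excluded library, and fits without the bird block. Summing contigs by ID stem, leaving out bird 40 or bird 27, bird number as a covariate and 2 surrogate variables (sva 3.50.0) were added after seeing the data. Other assignments of birds to groups were refitted, 40 per region for treatment and 21 each for region and interaction, the real one included. The refits for region and interaction used 9 grid points in the dispersion estimate to save time, a setting that called 27453 contigs for the real region labels.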

Results

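The brains of incubating female tree swallows (Tachycineta bicolor, a cavity-nesting songbird) were sampled to ask how expression responds to a social challenge. Of 20 wild birds, 10 faced a 30-minute simulated territorial intrusion and 10 were unchallenged controls. Each bird gave a ventral and a dorsal library, which the labels call ventral SBN and dorsal SBN and place in the diencephalon. The 40 libraries fell into ventral control (n = 10), ventral intrusion (n = 9), dorsal control (n = 10) and dorsal intrusion (n = 10), plus 1 ventral intrusion library, that of bird 21, which the submitters marked as excluded and which entered no group mean. Each bird is a separate animal, so the spread between libraries of a group includes the difference between individuals.

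Each library held counts for the same 207747 contigs, of which 6402 had no count in any library. Total counts per library ran from 16644029 to 32454096, with a median of 20410075.5. They averaged 22105917 ± 4227188 in ventral control, 20536442 ± 1520267 in ventral intrusion, 22003121 ± 3734029 in dorsal control and 21706279 ± 2987456 in dorsal intrusion libraries (SD). A library held on average 149371 ± 6916 contigs with at least 1 count in ventral control, 146563 ± 2300 in ventral intrusion, 147266 ± 4912 in dorsal control and 146825 ± 3758 in dorsal intrusion. The files do not pair contig IDs with gene names, so contigs are named here by ID, and what they encode is not given in the sources used here. Some IDs share a stem and differ in a final t number. There were 166890 stems, of which 21160 held several contigs.

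Region was the main axis of variation. The first principal component of log2 CPM (counts scaled to a common library total) over 52949 contigs held 20% of the variance and set ventral against dorsal libraries, and the second held 15.7%. The libraries of bird 40, an intrusion bird, lay the other way round: its library labelled ventral had a score of 18.4 among the dorsal libraries, and its library labelled dorsal had a score of -39 among the ventral libraries. The dorsal intrusion library of bird 21, at -4, lay between the ventral control libraries of bird 35, at -4.8, and bird 33, at -0.4.

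**Figure D1:**
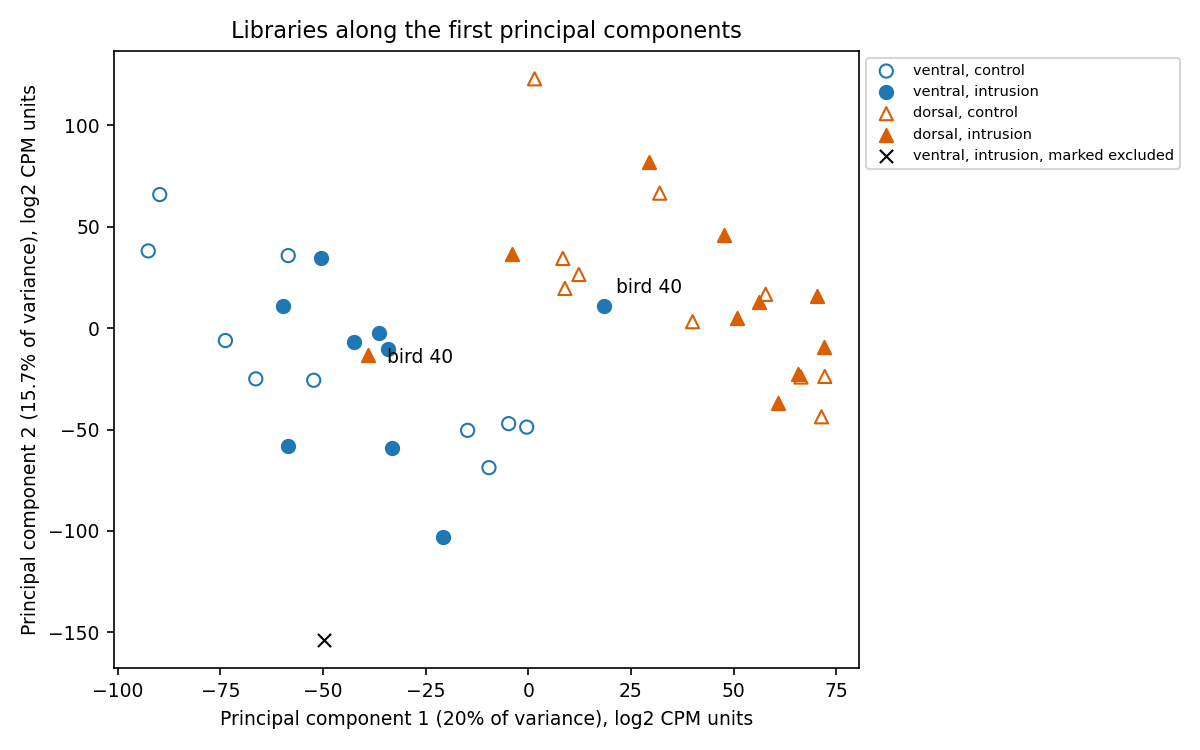
Scores of the 39 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, with the excluded library projected onto them. Circles are ventral and triangles dorsal libraries, open symbols are controls and filled symbols intrusion birds, and both libraries of bird 40 lie on the side of the other region, while the dorsal library of bird 21, at -4 on the x axis, lies where the regions meet.

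The first question was which transcripts of the ventral region differed between challenged and unchallenged females. No contig passed the test, and the contigs of smallest p differed by 1.7-fold to 3.39-fold between group means as fitted. Contig tree_swallow008166t1 averaged 81.4 ± 30.1 CPM in ventral intrusion birds (SD, n = 9) and 47.8 ± 6.98 CPM in ventral controls (SD, n = 10), a log2 fold change of 0.77 ± 0.16 (SE). It was above every control in 7 of the 9 intrusion birds. Contig tree_swallow007169t1 averaged 3.61 ± 1.07 CPM with intrusion and 1.56 ± 0.81 CPM without, with a log2 fold change of 1.22 ± 0.25 (SE), and 5 of 9 intrusion birds were above every control. In the other direction, tree_swallow007179t2 averaged 0.65 ± 0.10 CPM with intrusion against 1.17 ± 0.26 CPM in controls, with a log2 fold change of -0.85 ± 0.16 (SE), and all 9 intrusion birds were below every control. Contig tree_swallow011382t9 averaged 0.64 ± 0.38 CPM against 2.18 ± 0.82 CPM, with a log2 fold change of -1.76 ± 0.37 (SE), and 2 of 9 intrusion birds were below every control. The adjusted p of all 4 contigs was 1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment over 71490 contigs).

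In edgeR, 0 of the 71490 ventral contigs passed a false discovery rate of 0.05, and 2650 had an unadjusted p under 0.05, where 3574 would be reached by uniform p-values. DESeq2 and 2 forms of limma-voom also called 0 contigs. Of the 53384 contigs with a mean of at least 1 CPM, 92.04% had a 95% confidence interval of the fold change within 2-fold in either direction, so larger differences were excluded for most well-covered contigs, contig by contig. A difference of 1.5-fold could be missed at this number of birds, since 22.4% of such simulated changes were called.

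The same question was asked of the dorsal region. The contig of smallest p was tree_swallow008166t1, which ranked 2 by p in the ventral region. It averaged 62.8 ± 14.8 CPM in dorsal intrusion birds (SD, n = 10) and 40.9 ± 4.92 CPM in dorsal controls (SD, n = 10). Its log2 fold change was 0.62 ± 0.11 (SE), and 9 of the 10 intrusion birds were above every control. Contig tree_swallow023641t1 averaged 3.48 ± 1.67 CPM with intrusion and 1.43 ± 0.55 CPM without, a log2 fold change of 1.29 ± 0.26 (SE), with 7 of 10 intrusion birds above every control. The contigs tree_swallow007890t2 and tree_swallow007890t1, which share an ID stem, had lower means with intrusion, at 4.55 ± 0.86 against 7.04 ± 1.52 CPM and at 11.4 ± 2.02 against 16.4 ± 3.28 CPM. Their log2 fold changes were -0.63 ± 0.13 and -0.52 ± 0.12 (SE), and for each of them 8 of 10 intrusion birds were below every control. The adjusted p of these 4 contigs was also 1 in edgeR, over 68907 contigs.

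**Figure D2:**
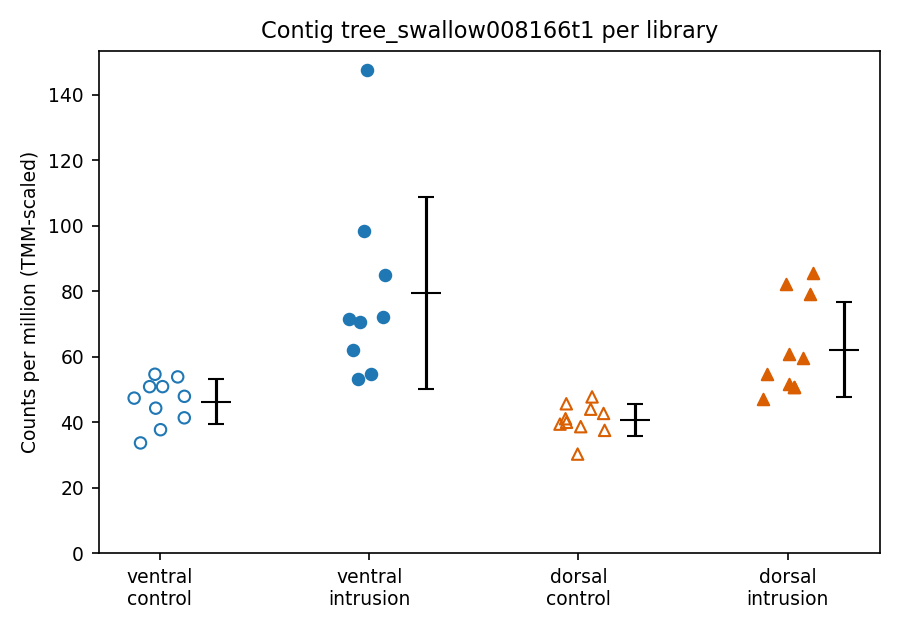
Level of contig tree_swallow008166t1 in CPM (y axis), scaled by TMM over all libraries, in each library of the 4 groups (x axis). Each symbol is 1 bird, with the group mean and SD beside it, and the highest value, 147.6 CPM, is the ventral intrusion library of bird 34.

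In edgeR, 0 of the 68907 dorsal contigs passed the threshold and 1890 had an unadjusted p under 0.05, where uniform p-values would give 3445. Both forms of limma-voom called 0 contigs. DESeq2 called 3. They were tree_swallow008166t1 with an adjusted p of 0.0451, tree_swallow023641t1 with an adjusted p of 0.0454, and tree_swallow021090t2 with an adjusted p of 1.27e-08. Over the 12 alternatives of the first the adjusted p ran from 0.0451 to 1, and over the 11 of the second from 0.0454 to 1. The third is named after its values were seen. It had counts in 4 of the 20 libraries, with means of 2.07 CPM with intrusion and 2.20 CPM without, although DESeq2 fitted a log2 fold change of -22.19. The filter on low counts removed it in edgeR, which without that filter called 0 dorsal contigs. Of the 53004 dorsal contigs with a mean of at least 1 CPM, 93.89% had a 95% confidence interval within 2-fold.

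Whether the intrusion acted alike on both regions was asked across contigs and by a test of the interaction. Here the effect was the difference of group means of log2 CPM, not the fold change fitted by edgeR. Over 53168 contigs of at least 1 CPM in the 19 birds with both libraries, ventral and dorsal effects correlated with Pearson's r = 0.596. Spearman's rho was 0.456, and 65.2% of contigs had the same sign in both regions. Contigs are not independent replicates, and both libraries of a bird share that bird's own deviations. When whole birds were reassigned to treatment at random 100 times, r had a median of 0.549 and a range of 0.191 to 0.801, so the observed correlation did not stand apart (permutation p = 0.3, one-sided). For rho the permutation p was 0.35.

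No contig passed the interaction test. The smallest p belonged to tree_swallow144257t1, whose mean in the dorsal region was 1.20 ± 0.90 CPM with intrusion and 0.63 ± 0.32 CPM without, and in the ventral region 0.46 ± 0.28 and 0.69 ± 0.41 CPM (SD). Its difference of log2 fold changes, dorsal minus ventral, was 1.41 ± 0.30 (SE). That of tree_swallow046127t1 was 0.93 ± 0.20, with 1.18 ± 0.42 against 0.89 ± 0.30 CPM in the dorsal and 0.83 ± 0.29 against 1.20 ± 0.35 CPM in the ventral region. Differences in the other direction were -1.54 ± 0.34 for tree_swallow037262t1 and -0.90 ± 0.21 for tree_swallow009068t4 (SE). All 4 had an adjusted p of 1 in edgeR. In edgeR, 0 of 80240 contigs passed and 2218 had an unadjusted p under 0.05, against 4012 for uniform p-values. Without bird 40, 0 passed and 4053 had an unadjusted p under 0.05. DESeq2 called 0, and edgeR without a filter on low counts called 63. Most of these 63 were not contigs of few counts. Their median total was 8503 counts, with counts in a median of 38 of 38 libraries. The smallest adjusted p in edgeR without the filter was 1.56e-84, although no contig passed with it, so these calls hang on the fit. Among contigs of at least 1 CPM, 95.46% had a 95% confidence interval of the interaction within 2-fold.

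The regions themselves differed widely. Of 80240 contigs tested within birds, 13234 were higher in the dorsal and 14186 higher in the ventral region, together 27420 or 34.17% (edgeR quasi-likelihood test with bird as a block, false discovery rate 0.05). Most of these differences were small, with a median absolute log2 fold change of 0.44. Differences of more than 2-fold were mostly toward the dorsal region, with 2052 contigs higher there and 981 higher in the ventral region. Beyond 8-fold there were 101 contigs higher in the dorsal and 11 higher in the ventral region. Without bird 40 the count was 30841, with 14560 higher in dorsal and 16281 higher in ventral libraries, and 27023 of the 27420 contigs were among them.

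Of the 21317 contigs past the threshold with a mean of at least 1 CPM, 354 were higher in the dorsal and 221 higher in the ventral library of every one of the 19 birds. A further 4707 had one direction in the 18 other birds but not in bird 40. The naming rule needs one direction in every bird, so it passed over these. The contigs named below are therefore not the largest region differences. Named by size among those with one direction in all 19 birds, tree_swallow067140t1 averaged 1.82 ± 0.74 CPM in dorsal and 0.50 ± 0.27 CPM in ventral libraries (SD, n = 19 each), a log2 fold change of 1.83 ± 0.18 (SE, adjusted p = 2.77e-08). Contig tree_swallow094274t1 averaged 1.78 ± 0.90 CPM in dorsal and 0.61 ± 0.28 CPM in ventral libraries, a log2 fold change of 1.53 ± 0.16 (SE, adjusted p = 7.91e-08). In bird 40 these 2 contigs barely differed. There tree_swallow094274t1 had 13 counts in each library, and tree_swallow067140t1 had 13 dorsal and 10 ventral counts. Higher in the ventral region was tree_swallow048497t1, at 7.36 ± 5.98 against 1.65 ± 2.08 CPM, with a log2 fold change of -2.35 ± 0.25 (SE, adjusted p = 1.15e-07). So was tree_swallow033303t1, at 4.22 ± 3.01 against 1.06 ± 1.27 CPM, with a log2 fold change of -2.22 ± 0.24 (SE, adjusted p = 9.09e-08). In bird 40 the former had 42 ventral and 2 dorsal counts, and the latter 41 and 4. Both thus kept the labelled direction there, but the naming rule selects for that. Levels varied widely between birds. Bird 38 had 11 ventral and 6 dorsal counts of the former, and 5 and 1 of the latter.

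The next counts are from CPM scaled over all 40 libraries, not over the 38 of the region test, so they differ slightly from those above. On that scale, whether or not they passed the test, 5271 of 53168 contigs of at least 1 CPM had one direction in each of the 18 birds other than bird 40. Of these, 3373 were higher in dorsal libraries, with a median log2 difference of 0.78, and 1898 were higher in ventral libraries, with a median of -0.57. The difference exceeded 2-fold for 1169 of the former and 243 of the latter, and 8-fold for 69 and 3. In a bird left out in turn, 92.8% to 98.4% of the contigs with one direction in the remaining birds kept that direction. In bird 40, 10.7% did. The counts over 19 birds therefore include 1 bird whose libraries run against their labels.

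**Figure D3:**
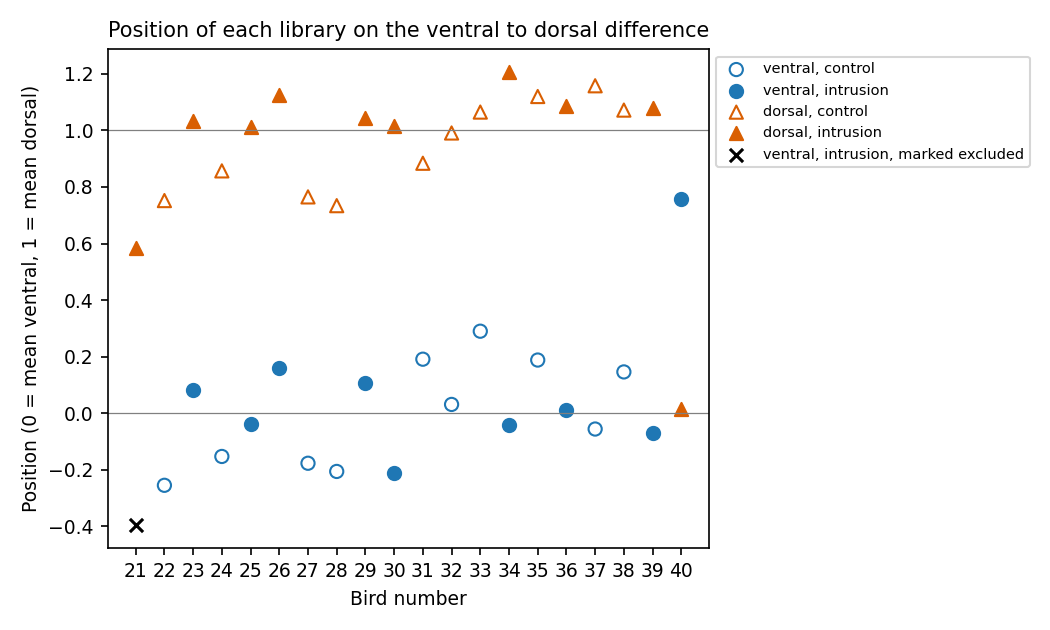
Position of each library (y axis, no unit) between the mean ventral profile at 0 and the mean dorsal profile at 1, over the 5271 contigs with one direction in the 18 birds other than bird 40, by bird number (x axis). The library labelled ventral of bird 40 lies at 0.756 and its library labelled dorsal at 0.016, while the other ventral libraries lie at most at 0.29 and the other dorsal libraries at least at 0.585. The contigs and both ends of the scale were set on those 18 birds, so the separation of their libraries is built in.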

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

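The tests on bird 40 were chosen only after its reversal had been seen. Single libraries were examined in 72 sets of group values, and 20 stood far from the rest of their group. Chance gives about 1 in 20 independent sets, but these sets share birds and contigs, and tree_swallow009209t3 was included after its values were seen, so their number is not a test.

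Bird 40 stood apart on both of its libraries. On the ventral to dorsal scale its library labelled ventral was the highest of its group at 0.756 (others -0.213 to 0.16), and its library labelled dorsal was the lowest of its group at 0.016 (others 0.585 to 1.207). That scale was set on the 18 other birds with both libraries kept, so the gap between their libraries is built in. The median correlation of the latter with all other dorsal libraries was 0.9245, against 0.9444 to 0.9578 for the rest of its group. A mixture in which tissue of the labelled region stays the larger part of both libraries would shrink the difference without turning it. Of the region contigs, 10.7% kept the direction of the other birds, which argues against such mixing alone. Where tissue of the other region is the larger part of a library, the difference can turn, so this share cannot exclude that. A library of another bird is argued against by bird-specific contigs, chosen without bird 40, over which its 2 libraries correlated at 0.851, above the 0.207 that was the highest between different birds, though below the 0.929 that was the lowest within the 18 birds on which these contigs were chosen. An exchange of regions between its 2 libraries remains a candidate explanation: the slope of its dorsal minus ventral difference on that of the other birds was -0.758, and with its sign turned lies within their range of 0.661 to 1.25. The direction share falls just short of this. In each other bird 92.8% to 98.4% kept the direction, so an exchange there would leave fewer than 10.7%. Whether an exchange arose at dissection, in the laboratory or in the labels is open, and no biological explanation was tested.

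The ventral control library of bird 27 had 6.646% of its counts in its 10 most abundant contigs (others of its group 2.506% to 3.08%), and tree_swallow009209t3 reached 23090 CPM in it against 1303 to 3222 CPM. In bird 28 the ventral control library had the largest total, 32454096 counts against at most 23295647, and the dorsal control library had 4.031% of its counts in 10 contigs against at most 3.276%. The median correlation with libraries of the same region was low in the dorsal control library of bird 24 (0.9306, others 0.9455 to 0.9547) and in the ventral intrusion library of bird 39 (0.9304, others 0.9461 to 0.9576).

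Among the named contigs, 1 library stood far from its group in several sets, in CPM scaled over all libraries. The ventral intrusion library of bird 34 had 147.6 CPM of tree_swallow008166t1 (others 53.29 to 98.38), and that of bird 30 had 0.4024 CPM of tree_swallow007179t2 (others 0.6106 to 0.7096). Bird 33 had the highest ventral control value of tree_swallow007169t1, 3.477 CPM (others up to 1.733), and of tree_swallow067140t1, 1.093 CPM (others up to 0.6392). For tree_swallow009068t4 the same birds stood out in both regions. Bird 33 had 3.328 CPM in the ventral and 3.449 CPM in the dorsal control libraries, and bird 39 had 5.119 and 2.177 CPM in the intrusion libraries. Bird 22 had the highest control values of tree_swallow037262t1, 1.134 CPM ventral and 2.083 CPM dorsal. The dorsal intrusion library of bird 21 had 9.436 CPM of tree_swallow048497t1 (others up to 4.777).

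In the library marked as excluded, 342 contigs were at over 4 times the level of every kept ventral library, where single kept ventral libraries had 0 to 31 such contigs, and 136 were over 4-fold below every one of them, against 0 to 11. Its median correlation with the kept ventral libraries was 0.8507, against 0.9304 to 0.9576 among these.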

How the results depend on the processing

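The alternatives that leave out a bird, sum contigs by ID stem or add covariates were chosen after seeing the data. Intrusion against control gave 0 contigs in the ventral region under every alternative run and in the dorsal region under all but DESeq2, which called 3, and a false discovery rate of 0.1 added none in edgeR. The cause of the DESeq2 calls was not tested. The interaction gave 0 contigs except with no filter on low counts, which called 63 (62 of them also tested with the filter), among them tree_swallow037262t1 with an adjusted p of 0.0238 (range over its alternatives 0.0238 to 1), and the cause was not tested. The region count ran from 14480 (6833 higher in dorsal, 7647 lower), with at least 5 CPM, which tests 27307 contigs and so allows fewer calls, to 30841 without bird 40 among the fits at 0.05. The numbers pair the libraries. With bird as a replicate block through a random effect, intrusion called 0 contigs in each region, and without the block the region comparison called 18719 (9731 higher and 8988 lower in dorsal) and the interaction 0. The correlation between regions was 0.456 (Spearman), 0.58 (at least 5 CPM) and 0.531 (without bird 40), none outside the reassigned birds. No contig named by the rule turned direction under any alternative that tested it, and 3 of their values passed the threshold only under one. The gene lists and summing by gene symbol were not run, since contigs carry no symbols. Depth limits the contigs of few counts: after the filter 71490 ventral and 68907 dorsal contigs were tested for intrusion.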

Other observations

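The tests of chance order and chance pairing below were chosen only after the patterns had been seen.

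Many contigs were characteristic of the individual bird. Over the 18 birds other than birds 21 and 40, 1859 of 53168 contigs (3.5%) had levels in the ventral and dorsal libraries that correlated above 0.9 across birds. Their median SD between birds was 0.88 on the log2 scale, against 0.326 for all contigs, and 692 of them had an SD over 1. Chance pairing of libraries is argued against: 1 of 101 pairings, the real one, gave as many, and the highest of the others gave 2 contigs. Reads trading between contigs of one ID stem would make such contigs fall as the rest of their stem rises, yet the median correlation with the other contigs of the stem was 0.789 (95% bootstrap interval 0.761 to 0.813, 1047 contigs). In comparison contigs of like level it was 0.632, but these were drawn from contigs with weaker agreement between the regions of a bird, so the contrast is not matched. The positive median argues against such trading for most of those 1047 contigs, of which 6.69% had a correlation below 0, against 5.28% of the comparison contigs. Another 727 are alone in their stem, and 85 with stem-mates under 1 CPM were not tested. The levels correlated across the 18 birds were not adjusted for treatment or for bird number, whose trend is described below, so both may enter them. Sequence differences between birds that change how reads match the contigs, and inherited differences in expression, may each leave such a pattern too. Neither was tested here, and the design has no group for either.

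Libraries also varied, most of all the ventral ones, with the bird number. Among 18 birds, with treatment in the model, the number took on average 17.8% of a contig's variance in ventral libraries, against a median of 5.75% in 999 random orders (permutation p = 0.001, the smallest these can give), which argues against a chance order. In dorsal libraries it took 11.2%, against a median of 5.83% (permutation p = 0.01). In edgeR 4427 contigs rose and 4525 fell with the number over the 18 ventral libraries, and 695 and 792 over 19 dorsal libraries, bird 21 included. Neither the position along the ventral to dorsal scale nor a score along the deviation of the excluded library accounts for the whole ventral trend. With the position in the model the permutation p was 0.001. With the score it was 0.007, with 12.6% left against a median of 6.22% in random orders. The score correlated with the number at Pearson's r = 0.619 and the position at 0.335, so part of the trend may go with either. The labels give no reason why the library was excluded, and RNA quality itself was not measured here and stays open. A property of the bird that both libraries share, such as an order of capture, and a batch of libraries may each underlie it and cannot be told apart here. The slopes of both regions correlated at 0.643 across contigs, within the random orders of whole birds (permutation p = 0.31). The bound set beforehand, the 95th percentile of 0.731, was not reached. It cannot exclude a shared property, because random orders of whole birds already gave a median of 0.603. Intrusion and control birds are spread along the numbers, and with the number in the model 0 contigs passed for intrusion in either region.

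A response of tree_swallow008166t1 to the intrusion in both regions was a hypothesis from its having the first or second smallest p in each. With both libraries of a bird summed, it had the smallest p of 92688 contigs, with a log2 fold change of 0.67 ± 0.12 (SE), and 9 of 9 intrusion birds were above all 10 controls. Its adjusted p was 0.927 in edgeR, so this may still be the extreme of many contigs. That miss does not exclude a response. The summed test called 22.4% of simulated 1.5-fold changes, but these were in contigs drawn at random from all 92688. Recovery for a contig at the level of tree_swallow008166t1 was not simulated, so the bound set beforehand cannot decide. The contig was picked on the same birds.

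Other assignments of the birds to groups gave the following. In the ventral region 40 of 40 splits gave at least the 0 contigs of the real one, with 1 as the highest of the others, and in the dorsal region likewise 40 of 40, with 1 as the highest. For the interaction 21 of 21 reassignments did, with 0 as the highest. With a real count of 0 no split can give fewer, so these 3 counts say nothing about chance. For the region comparison, 1 of 21 assignments, the real one, gave as many as 27420 contigs. The highest of the others gave 19148 with the labels of 3 of 19 birds turned. That the real one ranked first argues against a chance assignment, though 1 of 21 is the smallest share these refits can give. The real dorsal split had 1890 contigs with an unadjusted p under 0.05, the fewest of the 40, whose others had a median of 3457 and reached 8815. Without bird 40 the real split had 2735, and the other splits were not refitted without it.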
